A study of Homo sapiens with 8 samples.

How the data were processed

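RNA was sequenced from 4 human cancer cell lines, each cultured untreated or with 20 ng/ml IFN-gamma, with a time of 72 hours given in the labels. There are 8 libraries, 1 per line and arm. Groups were taken from the sample labels. Per the labels' protocols, cells grew in RPMI medium with 10% serum and RNA was extracted with TRIzol. The labels name both a poly(A) stranded SMARTer kit and a QuantSeq 3' mRNA forward kit, and which of them made these libraries is not settled here. Per the submitters' processing notes, Bowtie2, edgeR and the genome build hg19 were used. Their versions, the gene annotation, the counting tool and the use of strand in counting are not given in the sources used here. A gene that overlaps another, or has an antisense partner or a near-identical copy, is therefore uncertain.

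The authors deposited 1 table with raw counts per gene and, beside them, log2 normalized values, per the file headers. The log2 values behave as log2 of a scaled count plus 1, with 1 factor per library at high counts, and the scaling method is not stated. Whole-number counts were used for every main result, and the log2 values only for 1 alternative. The table has 25737 rows and 24462 gene symbols. Rows were summed by symbol, which affects 286 symbols. No per-sample column was left unused (0 columns).

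Total counts per library ranged from 6559933 to 9291154. Genes were kept by edgeR's filterByExpr by treatment (minimum count 10, minimum total 15), which left 13457 genes. Counts were scaled by TMM. Since the same line is in both arms, cell line was a term in the model, and treatment was tested by edgeR's quasi-likelihood test (glmQLFit and glmQLFTest, edgeR 4.0.16, R 4.3.3) with Benjamini-Hochberg adjustment at 0.05 and 3 residual degrees of freedom. The standard error of a log2 fold change is its size divided by the root of the F statistic. As a check of the pairing, deviations of log2 CPM from the arm means correlated across genes at 0.84 to 0.90 between the 2 libraries of a line, and at most at -0.10 between libraries of different lines. Subtracting the arm means itself pushes the correlations between lines below 0, so their sign adds nothing to this check. The labels name no replicate culture of any line, so the 4 lines stand as replicates. The p-values and standard errors rest on the spread of the response between lines, as estimated by a fit that shares information across genes. An exact paired sign permutation of 4 lines cannot give a two-sided p under 0.125.

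Gene lists were fixed before the data were examined. Lists with at least 3 tested members (25 of 29) were tested by camera on voom values (limma 3.58.1) with a preset inter-gene correlation of 0.01, beside camera with an estimated correlation and fry. Differences of the response between lines were tested as interaction terms, for both lung lines against the other lines and for each line against the other 3. The response of a single line is a log2 ratio of CPM with a prior count of 2 and has no replicate check. List medians of a line were placed among those of 10000 random lists matched on mean expression in 20 bins. For genes called higher with 0 counts in an untreated library, a fold printed for that line is a lower bound against 3 counts in that library. A ratio printed against 1 to 3 counts has an exact 95% binomial interval. The intervals cover counting error only. The bounds cover counting error in the untreated library only, since they take the treated count as exact, so they are loose where that count is small.

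The text names the 12 largest rises and 8 largest falls among called genes with 1 direction in all 4 lines and a mean log2 CPM of at least 3, a fixed set of 21 interferon-related genes, up to 4 members with the smallest p in each tested list, and up to 5 called genes of each interaction fit. Some genes that the rule takes are not reported here. Genes named outside this rule are said to be chosen after their values were seen. The alternatives were other scalings (RLE, upper quartile, library size alone), no filter, a filter of CPM 1 in 4 libraries, DESeq2 1.42.0, limma-voom, edgeR's likelihood ratio test, robust empirical Bayes, no cell line term, leaving out each line, the authors' log2 values with limma, and prior counts of 0.5 and 5.

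The methods were tested on simulated data with 200 changed genes. The changed genes had a mean log2 CPM of at least 3, and every gene took the dispersion of the fitted trend. For IFN-gamma against untreated (13267 genes), edgeR recovered 62% of genes raised by a log2 of 1, 68% of those lowered by 1, and 100% of those raised by 2 or 3, with 4 false calls among 169. For 1 line against the other 3 (13241 genes), it recovered 48% of genes raised by 2, 42% of those lowered by 2, 98% of those raised by 4 and 88% of those lowered by 4, with 7 false calls among 145. H1703 was the line changed in that fit. These shares do not carry over to genes with fewer counts or a spread above the trend. In a simulation with 1 list raised, camera called that list and 0 of the others. Genes were drawn independently there, so it does not test the preset correlation where list members vary together. In the data the estimated correlation of list members ranged from -0.03 (housekeeping) to 0.78 (proliferation).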

Results

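Transcript counts were measured by RNA sequencing in 4 human cancer cell lines, untreated and with IFN-gamma at 20 ng/ml for 72 hours, a cytokine of T and NK cells that signals through JAK kinases. The lines were A375 from skin melanoma, A498 from kidney carcinoma, H1703 from lung cancer, and a lung cancer line labelled 549. Each line gave 1 untreated and 1 treated library, 8 in all. Total counts were 6991610 and 6559933 in untreated and treated 549, 9291154 and 8901022 in A375, 6750962 and 8149074 in A498, and 7101076 and 8313169 in H1703. There is no replicate within a line, so errors below come from the edgeR fit over the 4 lines, which shares its estimate of spread across genes. They can understate how far the lines differ for 1 gene. JAK2, for instance, has an SE of 0.38 beside log2 ratios of 0.82 in 549 (58 to 95 counts) and 3.12 in A498 (66 to 654 counts).

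The first comparison asks which transcripts IFN-gamma changed across the lines. Among called genes with a mean log2 CPM of at least 3 and 1 direction in all 4 lines, the largest rises were of IDO1, the first enzyme of tryptophan breakdown, and of the guanylate-binding proteins GBP5 and GBP4. Of 13457 genes tested, 258 passed an adjusted p of 0.05 (edgeR quasi-likelihood test with a cell line term, Benjamini-Hochberg), 214 higher and 44 lower with IFN-gamma. Of the higher genes, 205 were up in all 4 lines, and of the lower genes, 39 were down in all 4. The count was 106 without A498, 153 without 549 and 455 without H1703. Without the cell line term edgeR called 0 genes (543 at an unadjusted p under 0.05), DESeq2 73 and limma-voom 3. With the term, DESeq2 called 1036, edgeR's likelihood ratio test 1319 and edgeR without a filter 884. Among the 214, 23 are SNAR family members, near-identical small RNA genes whose reads the counting could share.

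IDO1 had 1 count in each untreated library and 171 counts in treated 549, 900 in A375, 2843 in A498 and 577 in H1703 (edgeR adjusted p = 3.19e-05). Its ratio was 186-fold in 549, with an exact 95% interval from 33.0 to 7400, and 2559-fold in A498, with an interval from 459 to 101100. GBP5 likewise went from 1 count in each untreated library to 184, 151, 4201 and 28 counts in 549, A375, A498 and H1703. GBP4 rose by a log2 of 7.10 ± 0.51 (SE, 4 lines), UBD, a ubiquitin-like modifier, by 6.40 ± 0.37, XAF1 by 6.35 ± 0.78, GBP1 by 5.96 ± 0.37 and the transcription factor BATF2 by 5.48 ± 0.48. CASP1, the inflammasome caspase, rose by 5.20 ± 0.47 and SERPING1, the inhibitor of C1, by 5.17 ± 0.66, whose call was lost without A498 (adjusted p = 0.092). GBP1P1, a pseudogene that can share reads with GBP1, rose by 6.18 ± 0.50. For lines with 0 untreated counts a fitted change depends on the prior count, and against 3 counts in that library XAF1 was at least 239-fold higher in 549 and CASP1 at least 9.80-fold in 549 and 4.91-fold in H1703. On the same bound SERPING1 was at least 41.6-fold higher in A375 and 5.78-fold in H1703, and GBP1P1 at least 15.2-fold in 549 and 18.6-fold in A375.

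The STAT and IRF list of the pathway rose. It holds transcription factors and also IFI35 and NMI, which are not transcription factors. Of 10 tested members of the STAT and IRF list, 8 were higher and 0 lower (9 higher when adjusted over the list alone). IRF1 rose by a log2 of 4.57 ± 0.29 (SE, edgeR adjusted p = 0.00018), with ratios from 4.15 in H1703 to 5.57 in A375, and IFI35 by 3.16 ± 0.28. The list passed camera at an adjusted p of 2.04e-15, but not with an estimated correlation (adjusted p = 0.081). The receptor chains and kinases did not move as a list (camera adjusted p = 0.58, 1 of 5 members higher). JAK2 had a log2 change of 1.89 ± 0.38 (adjusted p = 0.045), a call that was lost without A375 (adjusted p = 0.10), A498 (0.16) or H1703 (0.057). IFNGR1, the ligand-binding receptor chain, had a log2 change of 0.05 ± 0.22 (adjusted p = 0.91), and its sign turned with library size alone, with upper quartile scaling and without A498. Of 12 feedback inhibitors 1 was higher (3 when adjusted over the list alone). The list was not called by camera (adjusted p = 0.13) and was called higher by fry (adjusted p = 0.027). The 1 higher member was SOCS1, at a log2 of 3.94 ± 0.46, from 0, 1, 12 and 3 counts in untreated 549, A375, A498 and H1703 to 7, 19, 234 and 30.

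Class I antigen presentation rose. Of 21 tested members, 17 were higher and 0 lower (18 when adjusted over the list alone), with a median log2 change of 2.40 (camera adjusted p = 9.62e-24, and adjusted p = 0.081 with an estimated correlation). TAP1, a peptide transporter subunit, rose by a log2 of 3.99 ± 0.24 (SE), NLRC5, the class I transactivator, by 4.85 ± 0.28, and the immunoproteasome subunit PSMB9 by 3.69 ± 0.33. The class I chains HLA-B and HLA-C rose by 3.41 ± 0.29 and 2.44 ± 0.24, and their partner B2M by 2.90 ± 0.28. HLA genes are polymorphic and resemble one another, so their counts can share reads. The constitutive proteasome list had 0 of 14 members called. It passed camera with a median of 0.15 (adjusted p = 0.043), not with an estimated correlation (adjusted p = 0.45) or by fry (0.22), nor with library size alone (0.087), without 549 (0.058) or without H1703 (0.52).

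Class II presentation also rose. Of 12 tested members, 5 were higher (8 when adjusted over the list alone, camera adjusted p = 5.56e-10, and adjusted p = 0.13 with an estimated correlation). CD74, the invariant chain, rose by a log2 of 6.56 ± 0.62 (SE), and from 0 untreated counts was at least 47.2-fold higher in 549 and 5.20-fold in H1703. HLA-DRA rose by 4.41 ± 0.38, from 456 to 5299 counts in A375 and 37 to 1519 in A498, against 0 to 8 in 549 and 0 to 1 in H1703, and the filter removed it when A375 or A498 was left out. The protease CTSS rose by 2.77 ± 0.28. CIITA, the class II master regulator, was removed by the filter on low counts. Its counts went from 6 to 491 in A375, 11 to 152 in A498, 0 to 8 in 549 and 1 to 2 in H1703.

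**Figure D1:**
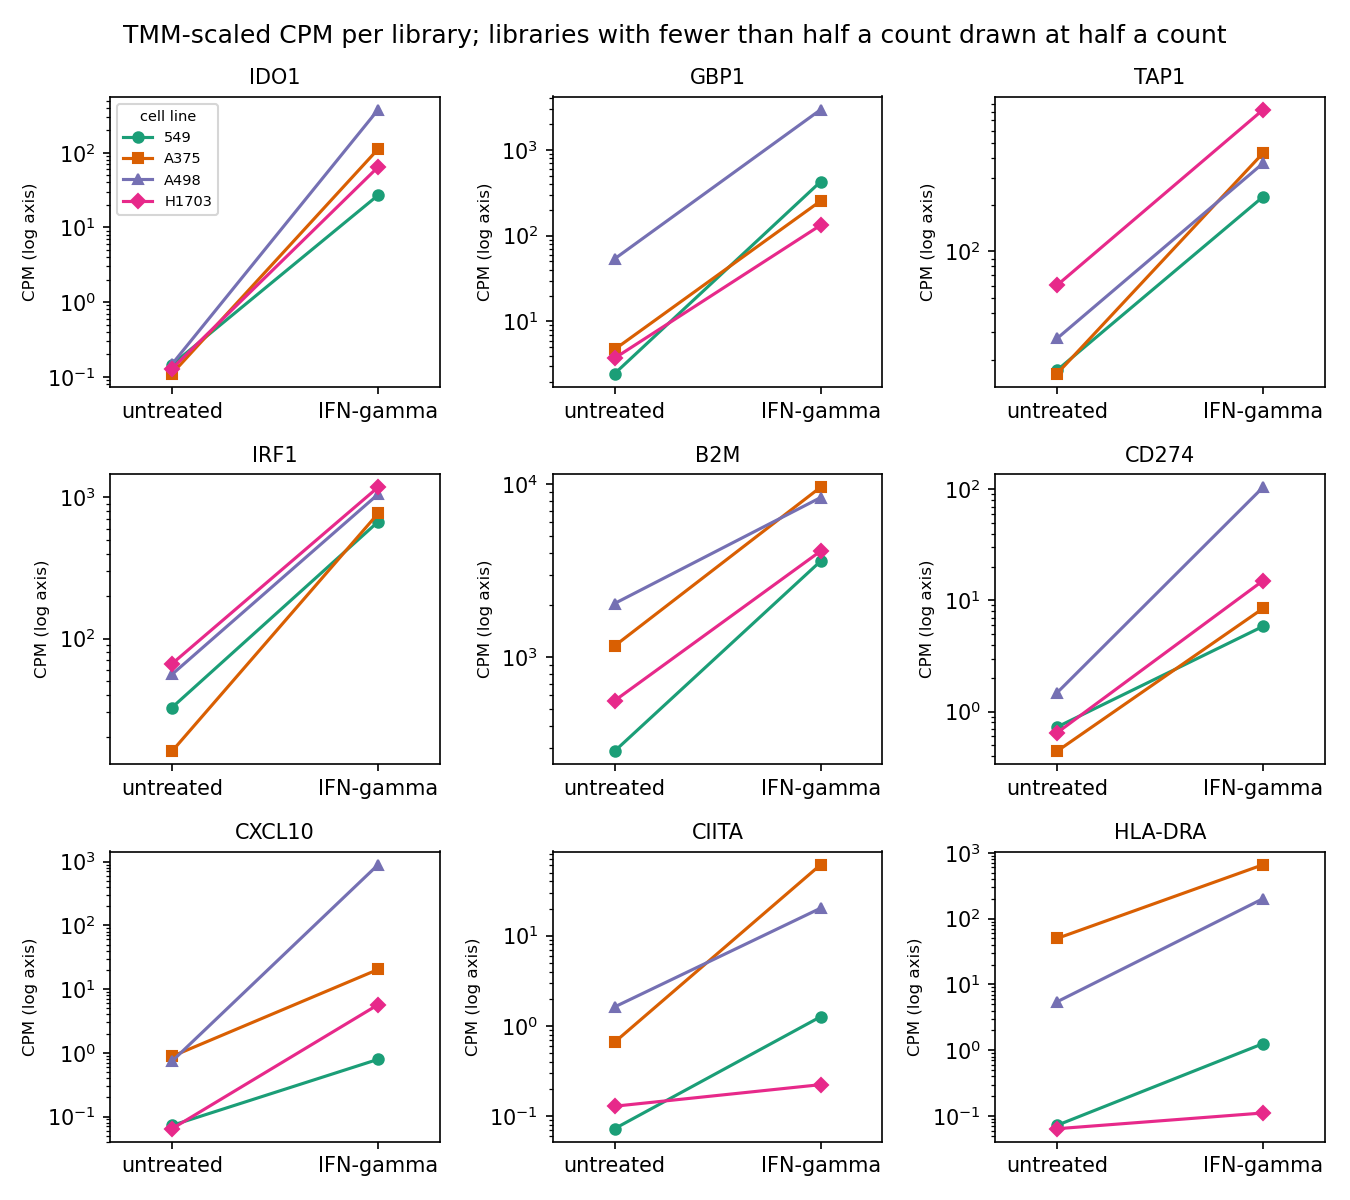
TMM-scaled CPM (log axes) of 9 genes, untreated and with IFN-gamma, 1 point per library and 1 line per cell line, with libraries at 0 drawn at 0.5 counts. TAP1, IRF1 and B2M rise in all 4 lines, while HLA-DRA reached 5299 counts in treated A375 and 1 in treated H1703.

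Other interferon-response lists rose too. All 5 tested guanylate-binding proteins were higher (camera adjusted p = 1.26e-10, and 0.093 as the adjusted p with an estimated correlation). Of 45 antiviral interferon-stimulated genes, 31 were higher and 0 lower (43 when adjusted over the list alone), with a median log2 change of 2.91 (camera adjusted p = 6.15e-45, adjusted p = 0.081 with an estimated correlation). Among them UBE2L6, the ISG15 conjugating enzyme, rose by 2.86 ± 0.17 (SE), OAS2 by 4.82 ± 0.34 (at least 9.44-fold in 549, from 0 counts) and PARP14 by 3.15 ± 0.24. Of 12 complement genes, 7 were higher (8 over the list alone, camera adjusted p = 2.49e-07, adjusted p = 0.13 with an estimated correlation), with C1R up by 3.14 ± 0.21. Of 22 cell death effectors, 7 were higher (14 when adjusted over the list alone, camera adjusted p = 7.39e-13, adjusted p = 0.093 with an estimated correlation), among them APOL3, up by 5.12 ± 0.47 and by at least 79.2-fold in 549, from 0 counts.

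Of 5 tested chemokines, 3 were higher (camera adjusted p = 4.18e-05, adjusted p = 0.22 with an estimated correlation). CXCL11, a CXCR3 ligand, rose by a log2 of 6.24 ± 1.12 (SE), and from 0 untreated counts was at least 18.5-fold higher in H1703. In 549 it went from 0 to 4 counts, too few to bound a rise. Its call was lost without 549 (adjusted p = 0.095), without A498 (0.11) or without H1703 (0.064). CXCL10 and CXCL9 were removed by the filter. CXCL10 counts went from 5 to 6738 in A498, 8 to 163 in A375, 0 to 51 in H1703 and 0 to 5 in 549, and CXCL9 reached 382 counts in treated A498 and 17 or fewer in the other treated lines. Of 12 checkpoint ligands 1 was higher (5 when adjusted over the list alone, camera adjusted p = 7.94e-05, adjusted p = 0.28 with an estimated correlation, fry adjusted p = 0.094). That 1 was CD274, which encodes PD-L1, at 4.79 ± 0.47, from 10 to 787 counts in A498 and 5 to 37 in 549. PDCD1LG2 was removed by the filter, with 7, 12, 94 and 21 counts in treated 549, A375, A498 and H1703 against 0, 0, 4 and 0. Of 10 NF-kB cytokines and adhesion molecules 2 were higher (8 when adjusted over the list alone, camera adjusted p = 4.14e-07, adjusted p = 0.17 with an estimated correlation), namely IL32 and ICAM1, the latter lost without 549 (adjusted p = 0.088) or without A498 (0.19).

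Several metabolic and stress lists passed camera with few or no single genes called. Of 10 tryptophan pathway genes 2 were higher (5 higher and 2 lower when adjusted over the list alone, camera adjusted p = 0.0057, adjusted p = 0.18 with an estimated correlation). These were IDO1 and WARS, the tryptophanyl-tRNA synthetase, up by 4.33 ± 0.43 (SE). Of 15 unfolded protein and amino acid stress genes, 0 were called over all genes and 11 were higher when adjusted over the list alone. Their median log2 change was 0.97 (camera adjusted p = 3.06e-08, adjusted p = 0.28 with an estimated correlation, fry adjusted p = 0.10). ATF3 had a log2 change of 2.40 ± 0.50 (adjusted p = 0.054), DDIT3 of 1.25 ± 0.29 and CHAC1 of 2.74 ± 0.66. Of 19 p53 targets 3 were higher (10 when adjusted over the list alone, camera adjusted p = 0.00018, adjusted p = 0.12 with an estimated correlation), namely FAS, CDKN1A and GDF15. FAS was lost without A498 (adjusted p = 0.13), GDF15 without 549, A375 or A498 (0.12, 0.10 and 0.21), and CDKN1A without 549, A375, A498 or H1703 (0.13, 0.10, 0.092 and 0.076). Of 14 ferroptosis and cystine uptake genes 1, AIFM2, was higher (3 when adjusted over the list alone), and its call was lost without 549, A375, A498 or H1703 (adjusted p = 0.051, 0.14, 0.22 and 0.066). The list was not called (camera adjusted p = 0.79), and its median was -0.04 against a mean of 0.13.

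Some lists fell as lists with no single gene called. Of 17 cholesterol synthesis genes, 0 were called over all genes and 12 were lower when adjusted over the list alone, with a median log2 change of -0.78 (camera adjusted p = 3.86e-06, adjusted p = 0.28 with an estimated correlation, fry adjusted p = 0.10). DHCR7 had a log2 change of -1.49 ± 0.38 (SE, adjusted p = 0.088). Of 36 proliferation genes, 0 were called either way, with a median of -0.65 (camera adjusted p = 1.41e-10, adjusted p = 0.32 with an estimated correlation, fry adjusted p = 0.17). Of 19 OXPHOS genes 0 were called (median -0.43, camera adjusted p = 9.96e-07, adjusted p = 0.28 with an estimated correlation, fry adjusted p = 0.058). Of 27 ribosomal protein genes, a control list, 0 were called (median -0.16, camera adjusted p = 0.0026, adjusted p = 0.58 with an estimated correlation, fry adjusted p = 0.30), and the call was lost without A498 (adjusted p = 0.18). In 549 the ribosomal list lay the other way, with a median log2 ratio of 0.21 and 22 members up. The housekeeping list, a control, was not called by camera (adjusted p = 0.12) and was called lower by fry (adjusted p = 0.048, median -0.15). Camera did not call the epithelial-mesenchymal list (adjusted p = 0.79) or the renal tubule and hypoxia list (0.55). Of 4 tested lung epithelial markers 1, AKR1C1, was lower (2 when adjusted over the list alone, camera adjusted p = 0.027, adjusted p = 0.22 with an estimated correlation), and the list's call was lost without A498 (adjusted p = 0.23). AKR1C1 itself was lost without 549, A375 or A498 (adjusted p = 0.18, 0.099 and 0.15).

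The largest falls were smaller than the rises. AKR1C2, a steroid-reducing enzyme that can share reads with AKR1C1, fell by 1.71 on the log2 scale (SE 0.21, edgeR adjusted p = 0.0039), from 39834 to 14971 counts in 549, 604 to 120 in A375, 10588 to 3687 in A498 and 28 to 9 in H1703. NDRG4 fell by 2.43 (SE 0.42), and SORL1 and SESN3 had log2 changes of -2.02 ± 0.39 and -1.75 ± 0.29. VAV3 and TMEM37 had changes of -1.93 and -1.92, NDRG2 of -1.72 and ARRB1 of -1.70. Of these 8, AKR1C2 was called whichever line was left out. VAV3 was called without A375 or H1703 and removed by the filter without 549 or A498. NDRG2 was lost without 549 (adjusted p = 0.088), NDRG4 without 549 (0.20) or A375 (0.10), SESN3 without A375 (0.093) or A498 (0.092), TMEM37 without 549 (0.13) or A498 (0.15), and SORL1 and ARRB1 without 549, A375 or A498 (0.15, 0.13 and 0.15 for SORL1, 0.14, 0.089 and 0.13 for ARRB1).

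The second comparison asks whether the response differed between lines. A count of 0 calls here does not show an equal response. For CXCL11 in A375 against the other lines, edgeR estimated a log2 difference of -6.82 and did not call it. No gene passed an adjusted p of 0.05 for lung lines against other lines (edgeR, 0 of 13457, 603 at an unadjusted p under 0.05), with limma-voom 0 and DESeq2 7. For each line against the other 3, edgeR and limma-voom called 0 genes, with 485, 1153, 585 and 418 genes at an unadjusted edgeR p under 0.05 for 549, A375, A498 and H1703. DESeq2 called 10, 61, 19 and 14.

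Within single lines, which have no replicate check, list medians were placed among random lists of matched expression. The class I list had a median log2 ratio of 2.74 in 549, 2.18 in A375, 2.04 in A498 and 1.84 in H1703, each at percentile 100 of 10000 random lists. The stress list had 1.35 in 549, 1.62 in A375, 0.72 in A498 and 0.01 in H1703, at percentile 100 in 549 and A375, 99.98 in A498 and 54.5 in H1703. The cholesterol synthesis list had -0.85, -1.34, -0.73 and -0.02 in 549, A375, A498 and H1703, at percentile 0 in 549, A375 and A498 and 41.2 in H1703. The proliferation list had -0.69, -1.32, -0.41 and -0.03, at percentile 0, 0, 0.01 and 25.3.

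**Figure D2:**
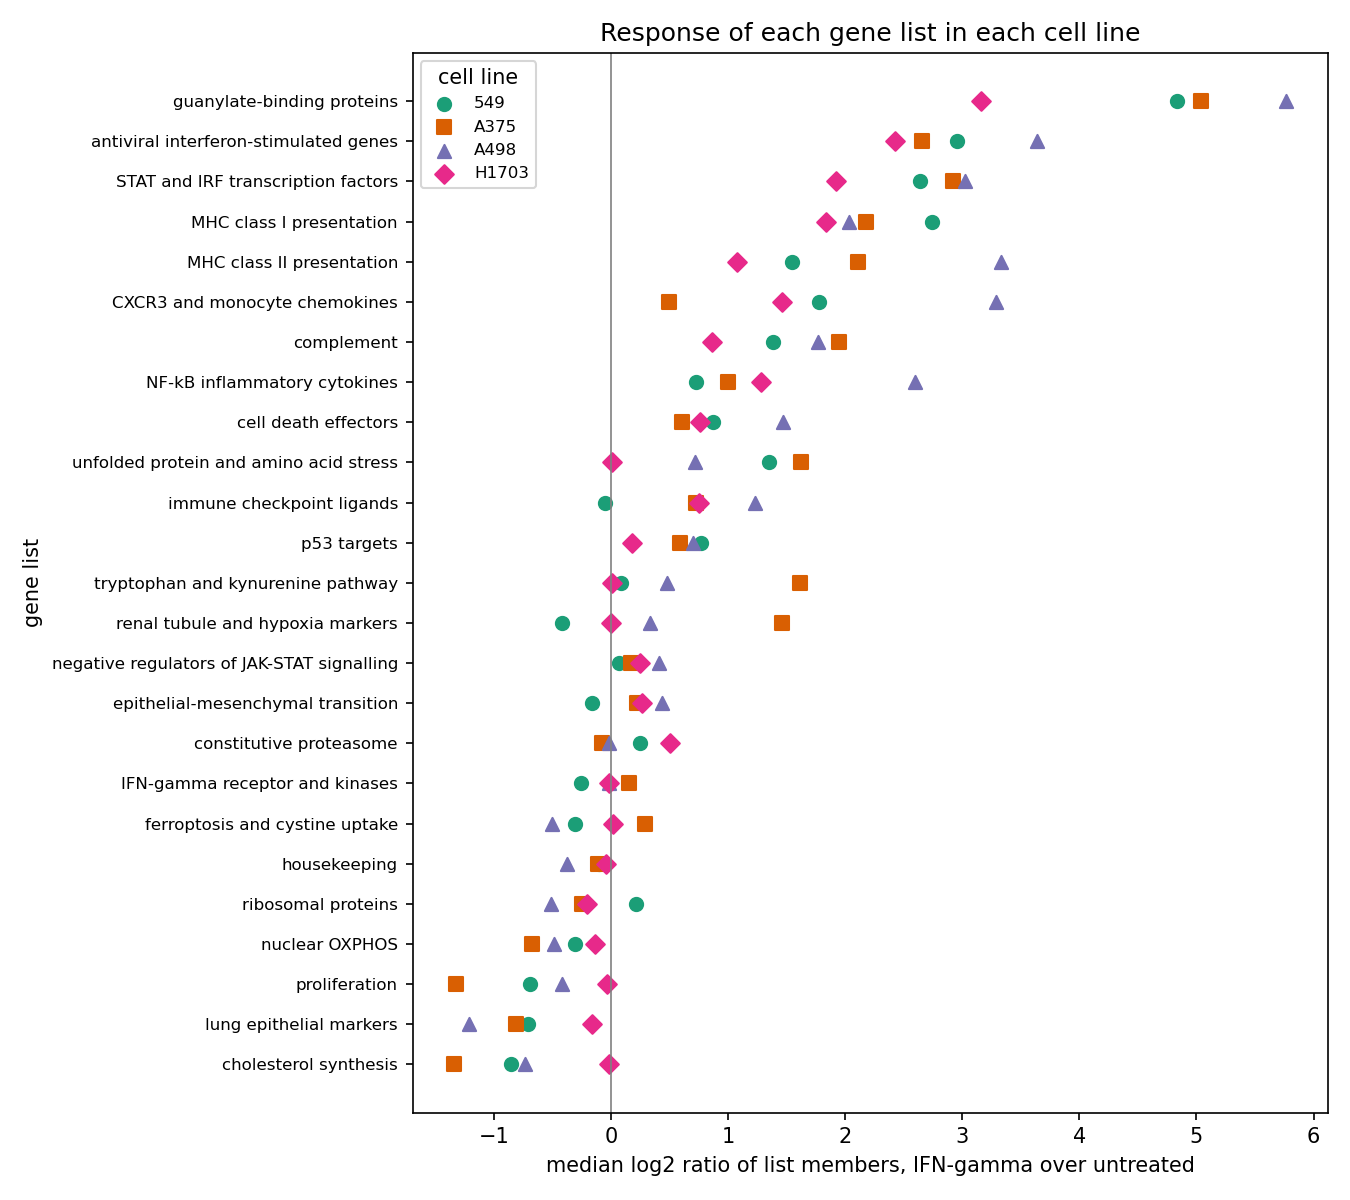
Median log2 ratio of treated over untreated CPM (horizontal axis) of the members of each tested gene list (vertical axis), 1 point per cell line. The 5 uppermost lists lie right of 0 in every line, and the H1703 points of the stress, cholesterol and proliferation lists lie at 0.01, -0.02 and -0.03.

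**Figure D3:**
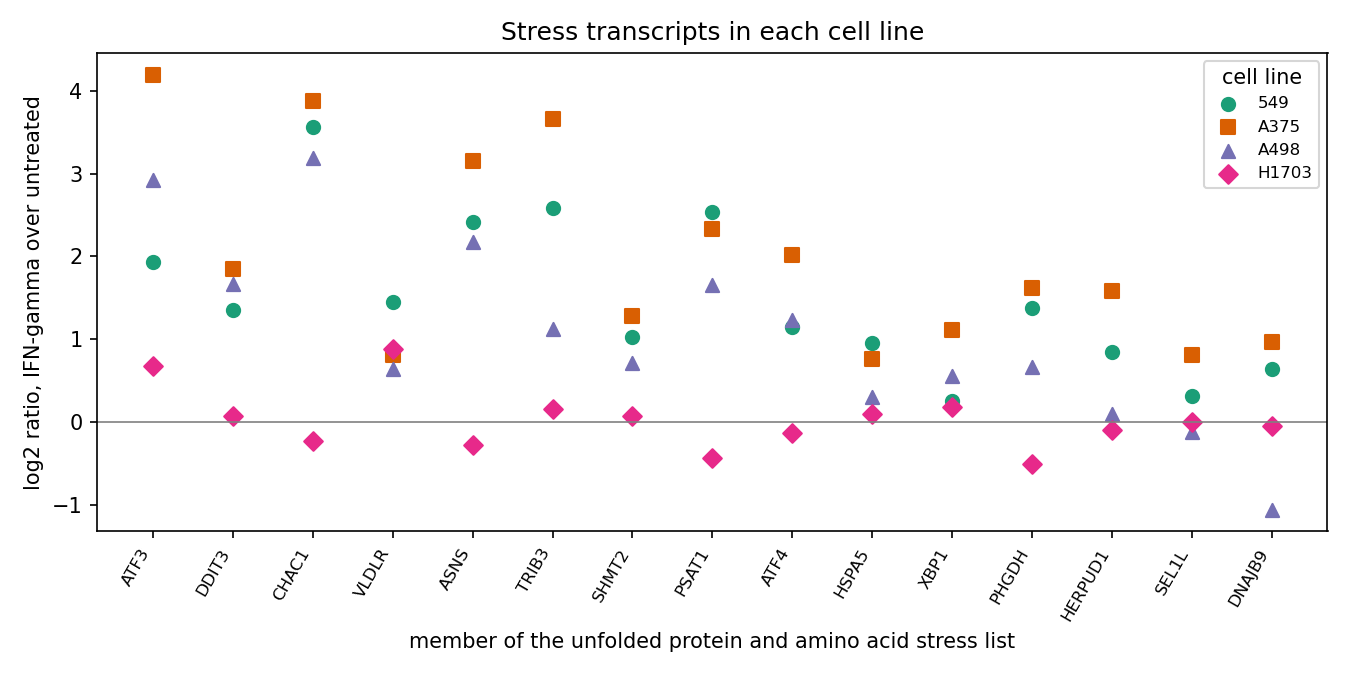
Log2 ratio of treated over untreated CPM (vertical axis) for each of the 15 members of the unfolded protein and amino acid stress list (horizontal axis), 1 point per cell line. The list medians are 1.35 in 549, 1.62 in A375, 0.72 in A498 and 0.01 in H1703.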

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

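The tests that weigh explanations here were all chosen after the results had been seen, as were the class II members named besides CIITA and CD74. Values from 4 libraries or 4 lines were screened for one standing apart in 68 groups, of which about 1 in 20 is expected to be picked out by chance, and 3 were. Untreated A375 had 9291154 counts against 6750962 to 7101076 in the other untreated libraries. The log2 ratio of IRF1 was 5.57 in A375 against 4.15 to 4.36 in the other lines, and that of TAP1 was 4.71 in A375 against 3.70 to 3.76.

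The other 3 results were lists, singled out because their response differed between A498 and the other 3 lines by an interaction test. The median difference in log2 change was 1.13 for class II presentation, 0.39 for cell death effectors and 0.39 for the epithelial-mesenchymal list. Their fry adjusted p-values were 0.0072, 0.0029 and 0.0072. A498 is a single pair of libraries here, assumed to vary like the other lines, so the difference has no replicate check of its own. The epithelial-mesenchymal list holds markers of both states, so its direction gives no direction of a transition. Class II members such as HLA-DRA had 0 counts in untreated 549 and H1703, where a log2 change depends on the prior count. The list-level interaction tests, and the need for a list to pass both camera and fry, were decided after the results were seen. Camera alone with the preset correlation passed 41 of the 125 pairs of list and fit, fry 3, and camera with an estimated correlation 0 (smallest adjusted p = 0.38).

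Of 18 class II list members, 13 had lower CPM in both treated lung lines than in treated A375 and A498, and IFI30, RFX5, RFXANK, RFXAP and HLA-DOB did not. The 13 include HLA-DQA1, at 0.266 CPM in treated A498, which is under the level of 3 counts there (0.398 CPM). Of the 13, 8 were lower in both lung lines without treatment too (7 of them with more than 3 counts in each of untreated A375 and A498), among them CD74, HLA-DRA, CTSS and HLA-DMA, a gap that exposure to IFN-gamma does not give. The gap was not confined to HLA genes. For CIITA and CD74, which are not HLA genes, the highest treated CPM in a lung line was 0.063 and 0.016 of the lowest in A375 and A498. Both are among the 13, so their levels are part of the pattern and do not test poor mapping of polymorphic alleles. That stays open for the HLA genes. For the rest of the treated gap weaker exposure stays open in both lung lines, since of 10 other lists that rose by camera and fry the median log2 ratio was at or above the lower of A375 and A498 in 5 for 549 and 3 for H1703, and CIITA, itself a member of the list, was not tested as a source. The difference in response between lung and other lines, which is not this gap in level, passed camera for the list (adjusted p = 0.014), but not with an estimated correlation (adjusted p = 0.53), fry (0.60) or any gene-level edgeR test.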

How the results depend on the processing

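The alternatives with SNAR genes summed, rows of a symbol kept apart, and DESeq2 or limma-voom without the cell line term were chosen after seeing the data. The cause of each change below was not tested. Genes changed numbered 258, and 884 without a filter (619 higher, 265 lower), 1036 with DESeq2 (631, 405), 1319 with the likelihood ratio test (766, 553) and 0 with no cell line term to pair the libraries (0, 0). Without the pairing DESeq2 called 73 and limma-voom 3 (69 and 3 higher, 4 and 0 lower). Limma-voom with the term called 305 higher and 82 lower genes, and the authors' log2 values 26 lower. Leaving out a line gave 106 to 455 genes, 102 to 315 higher and 3 to 140 lower. Of the 25 lists, 19 passed camera, 0 with an estimated correlation (8 at an unadjusted p under 0.05), 14 with fry and 16 without the pairing, and leaving out a line gave 17 to 19. DESeq2 called 7 genes for the lung lines, and 10, 61, 19 and 14 for 549, A375, A498 and H1703 against the other 3, where edgeR called 0.

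IFNGR1 (0.05) turned to -0.022 with library size alone and -0.015 with upper quartile, and ranged from -0.096 to 0.17 as lines were left out. The direction of the ferroptosis list turned with fry (median -0.042) and without 549 or A498, and its medians ranged from -0.26 to 0.011 as lines were left out. The other tested genes taken by the naming rule kept their direction in each setting in which the filter kept them. Genes named outside that rule were not followed across the settings. No per-line list median moved by more than the spread between lines under other prior counts or library size alone.

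Of 35 splits of the 8 libraries into equal groups, 32 can be fitted with the cell line term and 8 part all 4 pairs, so that no share under 0.125 can be reached. The real split gave 258 genes, 214 higher and 44 lower, the only 1 of the 8 with calls, and the highest of the others gave 0. It gave 19 lists and the highest of the others 16. The other splits of the 8 keep the IFN-gamma contrast in some lines and reverse it in others, so they are not free of the response. Their list counts therefore do not show how many lists camera calls without a response. Their gene counts of 0 do not either, since the response there adds to the spread. The fitted splits that part fewer pairs also gave 0 genes, and up to 18 lists, and they too hold the contrast in the pairs they part. A count of 0 allows up to 3 counts, or 0.329 to 0.474 CPM across these libraries, for counting error only. The filter removed CXCL9 and CIITA, and without it edgeR gave them adjusted p-values of 5.73e-05 each.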

Other observations

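The tests that weigh explanations in this part and the list-level interaction tests were chosen after the results had been seen, and so were the genes named here, though several belong to lists fixed in advance.

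Lineage markers separated the lines. SOX10, a melanocyte and neural crest factor, had 3952 counts in untreated A375 and at most 9 in the other untreated lines. PAX8, a kidney lineage factor, had 1552 counts in untreated A498, SOX2 1776 in untreated H1703 and ALDH3A1 6208 in untreated 549. In A375 the melanocyte gene DCT went from 760 to 150 counts and SOX10 from 3952 to 4269, in 1 pair of libraries, and the filter removed both from the tests. MITF, the 1 tested melanocyte marker, had log2 ratios of -1.39 in 549, -3.05 in A375, -1.21 in A498 and -0.12 in H1703. Its log2 change of -1.55 was not called over all genes (edgeR adjusted p = 0.092), but was when adjusted over the list alone (0 and 1 lower), a list with 1 tested member. Among leukocyte markers CD3E, CD3D and MS4A1 had 0 counts in every library, CD14 had 32 in untreated 549 and PTPRC 33 in untreated A375, and CD68, the 1 tested member, had a log2 change of 1.01 (edgeR adjusted p = 0.16), 0 higher over all genes and 1 when adjusted over the list alone. Of fibroblast and endothelial markers 2 were tested and 0 called, as for squamous markers, while COL1A2 had 433 and 445 counts in untreated and treated A375.

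The median log2 ratio of the amino acid stress list was 1.35 in 549, 1.62 in A375, 0.72 in A498 and 0.01 in H1703. In H1703 8 of its 15 members were up, among them VLDLR (0.88) and ATF3 (0.67), and in A498 13 were. ASNS counts went from 385 to 1889, 598 to 4700 and 546 to 2733 in 549, A375 and A498 and from 1531 to 1454 in H1703. Untreated levels differed too. In CPM, ASNS, CHAC1, PSAT1, PHGDH, ATF4 and DDIT3 were highest in untreated H1703 among the untreated lines. HSPA5, HERPUD1, DNAJB9, TRIB3, SHMT2 and VLDLR were lowest there. Whether the untreated level bears on the response was not tested. By gene, edgeR and limma-voom called 0 interactions for H1703, and DESeq2 called 14, among them the list members CHAC1 (adjusted p = 8.84e-08), ASNS (0.0016) and PSAT1 (0.0025). For the list the interaction gave an adjusted p of 3.35e-14 by camera with the preset correlation, 0.75 with an estimated one and 0.52 by fry. Treated IDO1 CPM in H1703 (64.4) was 2.39 times that in 549 (27.0), but below A375 (112.2) and A498 (377.4). The IDO1 transcript level thus does not order the lines as the stress list does. Protein and activity of IDO1 were not measured, so IDO1 as a source stays open. Scaling is argued against by a gap of 0.62 in the list median that remains with library size alone. Weaker exposure in H1703 stays open, since of 11 lists that rose by camera and fry its median was below that of every other line in 8 and not in 3, and a difference in the cells themselves was not tested.

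The 23 tested SNAR family members were all called higher. Of these, 39.1% had the same counts as another member in all 8 libraries. A bound of 50% was set for shared reads as the source of the number of calls, and it was missed, but copies with unequal counts may still share reads, so this stays open. With the family summed into 1 feature 222 genes were called. The summed family had a log2 change of 1.61 (edgeR adjusted p = 0.0039), which does not bear on shared reads, since each member was already higher.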
